A study of Mus musculus with 16 samples.

How the data were processed

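RNA-seq was carried out on skeletal muscle of wild-type (WT) mice and of mice labelled CHCHD4 Tg (Tg in what follows), each with or without treadmill training, which gave 4 groups of 4 libraries. CHCHD4 is a protein of the mitochondrial intermembrane space that oxidises the cysteines of imported proteins. Per the labels' protocols, RNA was purified with a column kit and libraries were made with a SMARTer mRNA-seq kit. The labels name neither the muscle nor the mouse strain, and they do not say whether the 4 libraries of a group came from separate animals, so p-values measure the spread between libraries. Per the submitters' processing notes, reads were handled with STAR 2.7.8a and RSEM 1.3.2 and the mm10 genome build. The deposited table holds RSEM expected counts for 55487 genes, not normalized, and 12.48% of its values were not whole. The annotation release is not given in the sources used here. RSEM divides reads among genes that share sequence, so values of near-identical copies are uncertain, and strand was not stated, so overlapping and antisense genes cannot be told apart. Gene positions were taken from the GENCODE annotation of GRCm38 by gene identifier without version.

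Expected counts were rounded to whole numbers. Genes were kept with filterByExpr by group, which left 17490, of which 17460 had a position. Library totals ranged from 40888325 to 61703724 counts, and at least 99.928% of each total fell in tested genes. TMM factors ranged from 0.924 to 1.285, the highest in WT untrained replicate 2. No pair of replicates had counts within sampling noise: the lowest chi-square per degree of freedom was 6.62. All 16 libraries entered a single edgeR 4.0.16 quasi-likelihood model with a mean per group (R 4.3.3), and 7 contrasts were tested: training in each genotype, Tg against WT at each training state, the difference between the training responses, and training and Tg averaged over the other factor. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The biological coefficient of variation was 14.14%. CPM are counts scaled to library size after TMM, given as mean ± SD over 4 libraries, and log2 fold changes (log2FC) carry a standard error (SE) from the quasi-likelihood F.

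Before the data were examined, 20 pathway lists and 11 cell type marker lists were fixed, together with the main model, the alternatives and the rule for naming genes. Of the 31 lists, 30 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. The rule named Chchd4, Triap1, Myod1, Cgas and Sting1 in each contrast. It added, among called genes with a mean CPM of at least 5, the 10 with the largest fold change in each direction, without unnamed gene models and sex-linked Xist and Y genes. It also took up to 4 called members of each list described, or where none was called up to 2 with the smallest p, and for the difference of responses the 5 genes with the smallest p. The text prints a part of the genes so named; any other gene named was chosen after its values were seen.

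The alternatives were RLE size factors, no filter, a filter of CPM of at least 1 in 4 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, leaving out each library, and fitting only the 8 libraries of a pairwise contrast. Alternatives added after seeing the data left out the 3 libraries with more than 10 CPM of Alb, a liver transcript, left out the 4 libraries with more than 10 CPM of Myh7, the slow-twitch myosin, or removed mitochondrial rRNA and 7SL RNA. Where libraries were left out, the 17490 tested genes were held fixed. This was settled after a first run in which the filter was applied again, which let in low-count genes (17687 to 17854 tested). Counts of called genes then ranged much as with fixed genes, but the correlation of the training responses ranged from -0.035 to 0.285. Correlations with shared control libraries were set against 100 simulations of unchanged groups. Shared calls were set against 20 such simulations and against splits of the WT untrained libraries, both added after the results were seen. Other splits of the libraries were all 35 for each pairwise contrast and 100, drawn with a seed, for the others. The pipeline was tested on simulated data for training in WT (17313 genes tested): of 100 genes changed 2-fold, 65 were called in the right direction, and of 100 changed 4-fold, 89 were, with 14 unchanged genes called.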

Results

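The transcriptome of skeletal muscle was measured in WT and CHCHD4 Tg mice with or without treadmill training, with 4 libraries in each of the 4 groups. The design asked which transcripts go with CHCHD4 and with exercise training. Mean totals were 47492836 counts in WT untrained, 47046158 in WT trained, 50530276 in Tg untrained and 53886144 in Tg trained libraries. A single mitochondrial ribosomal RNA, mt-Rnr2, took 23.1% to 29.6% of the counts of a library, and Ttn, which encodes the giant sarcomere protein titin, took 10.3% to 12.2%.

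Chchd4 (ENSMUSG00000034203.8, GRCm38 chromosome 6, 91462172 to 91473546) separated the genotypes in every library. It measured 7.90 ± 0.885 CPM in WT untrained, 8.14 ± 0.671 in WT trained, 20.3 ± 1.69 in Tg untrained and 21.8 ± 0.306 in Tg trained libraries (mean ± SD, n = 4). The WT libraries lay between 6.88 and 8.98 CPM and the Tg libraries between 18.1 and 22.2. Its log2FC in Tg was 1.36 (SE 0.083) without training and 1.42 (SE 0.083) with training, at adjusted p of 1.55e-07 and 1.64e-07 (edgeR). Training left no called difference in Chchd4: the log2FC was 0.04 in WT and 0.10 in Tg, with adjusted p of 0.90 and 0.68. Triap1, which encodes a small intermembrane-space protein of phospholipid transfer, was not called in any contrast. Its log2FC was -0.14 in Tg without training (adjusted p = 0.445) and -0.07 with training (adjusted p = 0.911). Myod1, Cgas and Sting1, which encode a myogenic transcription factor, a cytosolic DNA sensor and its adaptor, were likewise not called in any contrast.

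**Figure D1:**
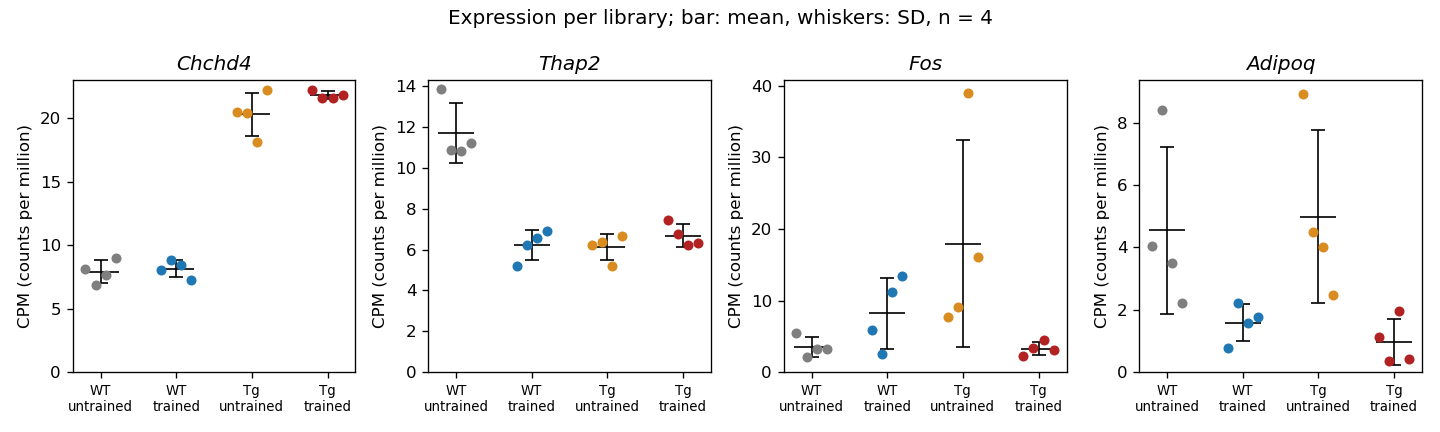
Normalised expression (CPM, vertical axis from 0) of Chchd4, Thap2, Fos and Adipoq in each library of the 4 groups; points are libraries, bars the mean and whiskers the SD (n = 4). Chchd4 lay between 6.88 and 8.98 CPM in WT and between 18.1 and 22.2 CPM in Tg libraries, while Thap2 was higher in WT untrained (11.7 ± 1.47 CPM) than in the other groups.

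Few genes were called between trained and untrained WT muscle. Of 25 called genes, 18 were higher and 7 lower in trained mice, and 12 of the 25 were unnamed gene models. Thap2 (log2FC -0.91, SE 0.106, adjusted p = 0.000478), Zfc3h1 (log2FC -0.82) and Tmem19 (log2FC -0.76), neighbours on chromosome 10, fell together, and Dynlt1b, a dynein light chain gene, fell by 0.72 on the log2 scale. Entpd4 (log2FC 1.02, SE 0.156), Rell1 (0.40) and Wipf2 (0.36) rose. Most of these levels set WT untrained libraries apart from all other groups: Thap2 measured 11.7 ± 1.47 CPM in WT untrained, 6.24 ± 0.736 in WT trained, 6.12 ± 0.637 in Tg untrained and 6.69 ± 0.558 in Tg trained libraries. Of the 25 genes, 21 were also called in the same direction between Tg and WT untrained libraries.

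As groups, markers of tendon and cartilage fell in trained WT muscle (11 of 11 with a negative log2FC, median -1.14, 0 called; 6 lower adjusted over the list alone; camera adjusted p = 9.91e-11), as did markers of adipocytes (median -0.86, 12 of 15 negative; 9 lower and 2 higher adjusted over the list alone) and genes of collagens and extracellular matrix (median -0.30, 26 of 29 negative; 0 adjusted over the list alone). Fibroblast markers fell by a median of 0.30 (11 of 14 negative, 1 lower adjusted over the list alone). Genes of nuclear-encoded oxidative phosphorylation (median 0.13, 68 of 71 positive), of glycolysis and glycogen (median 0.23, 24 of 26 positive) and of fatty acid uptake and oxidation (median 0.17, 25 of 28 positive) rose, with 0, 0 and 1 member called adjusted over the list alone. In all, 13 of 30 lists were called, and none was with an estimated correlation (lowest adjusted p = 0.584). Without WT untrained replicate 2 the oxidative phosphorylation median was -0.039 and the list was called lower (adjusted p = 0.00956), and glycolysis (median 0.047, adjusted p = 0.228) and fatty acid oxidation (median 0.02, adjusted p = 0.589) were not called. Without WT trained replicate 4 the medians were -1.84 for tendon and cartilage, -0.52 for collagens and -0.472 for fibroblast markers. Without WT trained replicate 2 they were -0.196 for collagens and -0.127 for fibroblast markers. Dynlt1b was not called without WT untrained replicate 4 (adjusted p = 0.0518), and Rell1 and Wipf2 lost their calls without 7 and 13 of the 16 libraries, each left out singly. The count of called genes was 16 without WT untrained replicate 4 and 10 when only the 8 WT libraries were fitted.

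In Tg muscle, no gene was called for training (0 genes in edgeR, lowest adjusted p = 0.132), although 1938 genes had an unadjusted p under 0.05 and DESeq2 called 132; limma-voom called 0. As a group the immediate early genes, which are transcribed within minutes of a stimulus, fell in trained Tg muscle: 25 of 25 had a negative log2FC with a median of -1.05, and 21 were lower adjusted over the list alone (camera adjusted p = 8.55e-30; adjusted p = 0.0148 with an estimated correlation). Klf4, a transcription factor gene, measured log2FC -1.40 (SE 0.248, adjusted p = 0.132) and Nr4a2, an orphan nuclear receptor gene, -2.22 (SE 0.45, adjusted p = 0.140). Adipocyte markers also fell (13 of 15 negative, median -0.69, 12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0397 with an estimated correlation). Their smallest p belonged to Lep, the leptin gene (log2FC -3.53), and Cidec, which encodes a lipid droplet protein (log2FC -2.74), both at adjusted p = 0.132.

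The other 11 called lists in Tg muscle were not called with an estimated correlation (adjusted p of 0.267 for fibroblast markers and above for the rest). Among them, mitochondrially encoded protein genes rose (median 0.34, 12 of 13 positive, 2 higher adjusted over the list alone; adjusted p = 0.409 with an estimated correlation), and so did disulfide relay substrates and twin CX9C or CX3C proteins, the family whose import CHCHD4 serves (median 0.15, 27 of 31 positive, 0 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Macrophage and monocyte markers fell (median -0.57, 17 of 18 negative, 1 lower adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Markers of fibroblasts and fibro-adipogenic progenitors (median -0.47, 13 of 14 negative, 9 lower adjusted over the list alone; adjusted p = 0.267 with an estimated correlation), of tendon and cartilage (median -0.74, 10 of 11 negative, 0 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation) and genes of collagens and extracellular matrix (median -0.25, 29 of 29 negative, 0 adjusted over the list alone; adjusted p = 0.578 with an estimated correlation) fell with them. Without Tg untrained replicate 3 the tendon list was not called (adjusted p = 0.051), and the medians were 0.207 for mitochondrially encoded and 0.101 for disulfide relay genes. Myh7, the slow-twitch myosin gene, varied within untrained Tg muscle, at 1.91, 64.3, 42.1 and 3.13 CPM in replicates 1 to 4, against 1.16 to 2.50 CPM in trained Tg libraries, and was not called. The count of genes was 93 without WT untrained replicate 2, 4 without Tg trained replicate 3, 1 without WT trained replicate 2 and 123 when only the 8 Tg libraries were fitted.

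**Figure D2:**
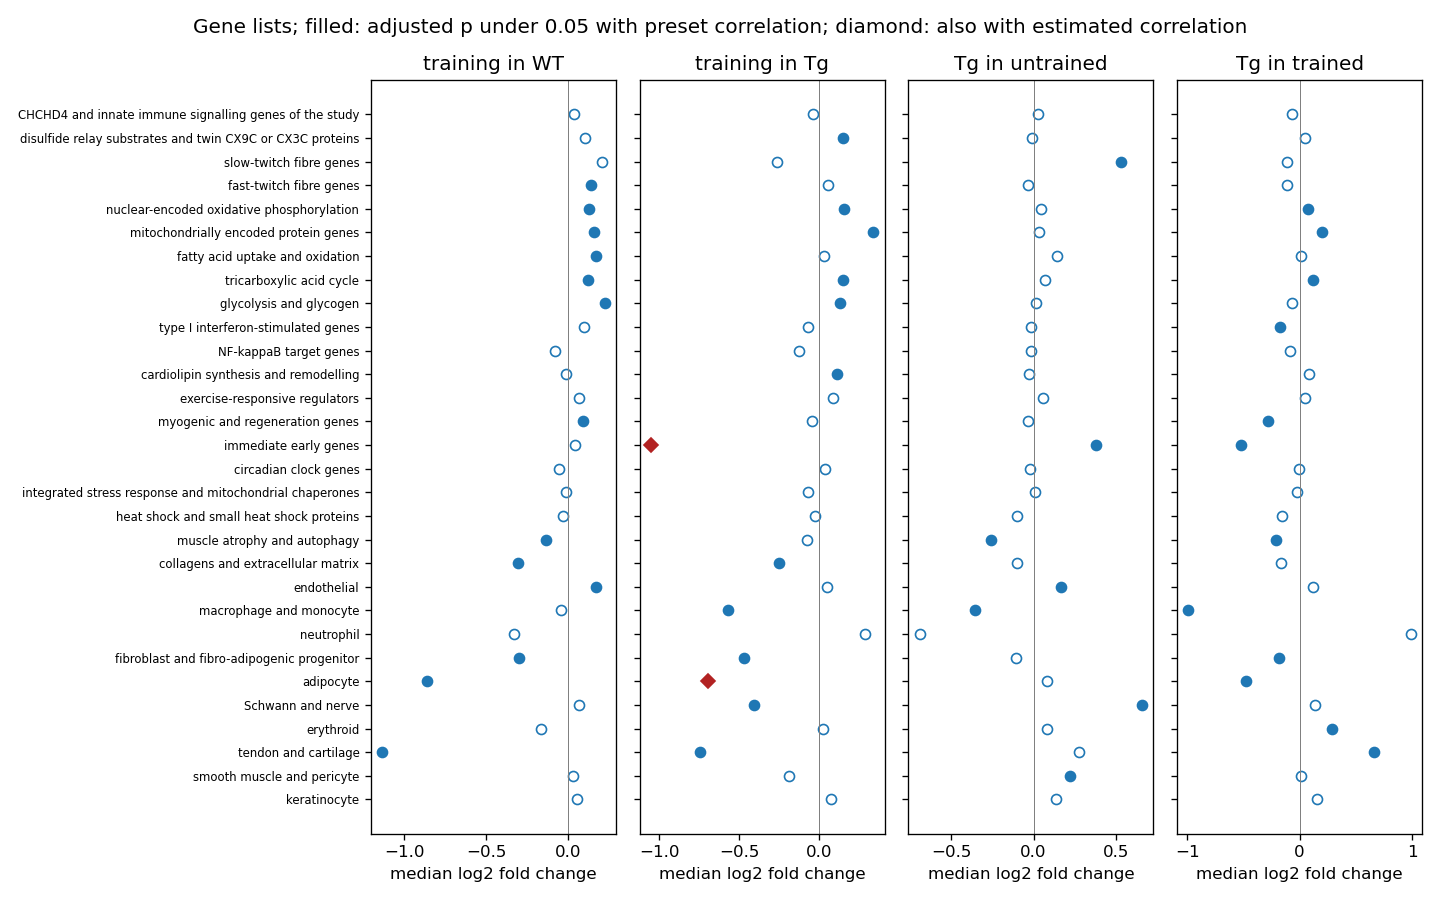
Median log2 fold change (horizontal axis) of the members of each of the 30 tested gene lists in the 4 pairwise contrasts; filled symbols had a camera adjusted p under 0.05 at the preset correlation, and diamonds also with an estimated correlation. Diamonds stand at the immediate early genes (-1.05) and the adipocyte markers (-0.69) for training in Tg.

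Without training, 130 genes were called between Tg and WT muscle, 87 higher and 43 lower, 42 of them unnamed models. Of these, 21 were also called in the same direction for training in WT, a contrast with the same WT untrained libraries. Thap2 and Zfc3h1, which set WT untrained apart, were among the lower genes. Their log2FC ran from -0.971 to -0.842 and from -0.902 to -0.738 with single libraries left out. Immediate early genes were higher in Tg: Fos measured 18.0 ± 14.5 CPM against 3.50 ± 1.44 (log2FC 2.36, SE 0.527), Egr1 had a log2FC of 1.97 (SE 0.411), Klf2 of 1.28 and Ier2 of 0.92. Of the 25 members, 4 were called higher (7 adjusted over the list alone; median 0.38; adjusted p = 0.571 with an estimated correlation). The median was 0.233 without Tg untrained replicate 3 and 0.618 without WT untrained replicate 2. Apold1, an endothelial early-response gene, rose from 4.10 ± 1.54 to 14.2 ± 2.20 CPM (log2FC 1.80, SE 0.272, adjusted p = 0.0063). G0s2, an inhibitor of triglyceride lipase, rose by a log2FC of 1.41, and Notch3, a receptor of vascular smooth muscle, by 0.54. Lower genes were Tmem267 (log2FC -1.38, SE 0.171), Ifi207, an interferon-inducible gene (-1.04), Slc2a3, a glucose transporter gene (-1.03), and Spns2, a sphingosine-1-phosphate transporter gene (-0.84).

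Slow-twitch fibre genes were higher as a group in untrained Tg muscle (13 of 18 positive, median 0.53, 0 called, 5 higher adjusted over the list alone; adjusted p = 0.571 with an estimated correlation). Markers of Schwann cells and nerve had a median of 0.66 (12 of 12 positive, 0 adjusted over the list alone; adjusted p = 0.833 with an estimated correlation). Genes of muscle atrophy and autophagy were lower (median -0.26, 20 of 21 negative, 0 adjusted over the list alone; adjusted p = 0.833 with an estimated correlation). Among other cell type markers, endothelial (median 0.17; adjusted p = 0.833 with an estimated correlation) and smooth muscle and pericyte markers (median 0.22; adjusted p = 0.647 with an estimated correlation) were higher and macrophage markers lower (median -0.36; adjusted p = 0.968 with an estimated correlation), with 0 endothelial, 2 smooth muscle and 0 macrophage members called adjusted over the list alone. Without WT untrained replicate 2 these medians were 0.089, 0.099 and -0.185, and the endothelial and macrophage lists were not called; nor were they without Tg untrained replicate 4 (medians 0.099 and -0.215). Myh7 was above 10 CPM in Tg untrained replicates 2 and 3, and without the 4 libraries of the series above that level the slow-twitch median was 0.069 and not called (adjusted p = 0.358). There the Schwann median was -0.01 and 32 genes were called. Leaving out a single library gave 57 genes (WT untrained replicate 1), 53 (WT untrained replicate 3), 78, 48, 43 and 66 (Tg untrained replicates 1 to 4), 73 (Tg trained replicate 2) and 86 (Tg trained replicate 4). Fos and Ier2 each lost their call without 13 of the 16 libraries left out singly, G0s2 without 11, Notch3 and Ifi207 without 8 and Egr1 without 7, while Apold1, Klf2, Tmem267, Spns2 and Chchd4 kept theirs without each; Fos had a log2FC of 1.66 without Tg untrained replicate 3. Slc2a3 lost its call without Tg untrained replicate 3 or 4 (adjusted p of at most 0.0593), the atrophy list without WT untrained replicate 2 (median -0.084) and the Schwann list without Tg untrained replicate 3 (median 0.317). Only the 8 untrained libraries gave 40 genes.

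With training, 2 genes were called between Tg and WT muscle, against 1395 at an unadjusted p under 0.05. Chchd4 was higher, and Csf2ra, which encodes a subunit of the GM-CSF receptor, was lower (log2FC -1.12, adjusted p = 0.0177) at mean levels of 0.949 CPM in WT and 0.435 in Tg; it was chosen after its values were seen. Markers of macrophages and monocytes were lower in trained Tg muscle (18 of 18 negative, median -0.99, 15 lower adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), with Itgam at log2FC -1.21 (SE 0.293, adjusted p = 0.287) and C1qb, a complement gene, at -1.28 (SE 0.328, adjusted p = 0.338). Type I interferon-stimulated genes were also lower (40 of 44 negative, median -0.17, 5 lower adjusted over the list alone; adjusted p = 0.215 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase gene, measured log2FC -1.18 (SE 0.204, adjusted p = 0.111). Markers of adipocytes (13 of 15 negative, median -0.48, 2 lower adjusted over the list alone; adjusted p = 0.472 with an estimated correlation) and of fibroblasts and fibro-adipogenic progenitors (11 of 14 negative, median -0.19, 4 lower and 1 higher adjusted over the list alone; adjusted p = 0.575 with an estimated correlation) were lower too, as were immediate early genes (23 of 25 negative, median -0.53, 8 lower adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). Erythroid markers (6 of 6 positive, median 0.28, 0 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation) were higher. Tendon and cartilage markers were higher (11 of 11 positive, median 0.67, 0 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation). The tendon median was 0.373 without WT trained replicate 2 and 1.32 without WT trained replicate 4, and the interferon median -0.092 without WT trained replicate 1. The fibroblast list was not called without WT trained replicate 1 (median -0.085) or 4 (median -0.066), and its median was -0.311 without WT trained replicate 3. Without WT trained replicate 2, 16 genes were called, and 11 without WT untrained replicate 2. The count was 1, with Chchd4 still called, without WT trained replicates 3 or 4 or any of the Tg trained libraries. DESeq2 called 55 genes.

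**Figure D3:**
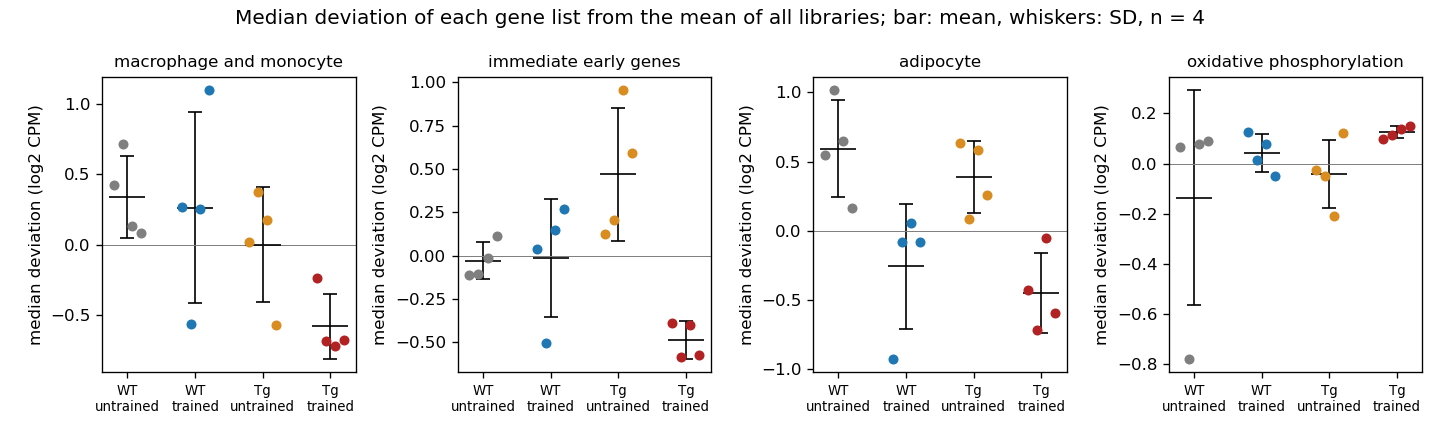
Median deviation (log2 CPM, vertical axis) of 4 gene lists in each library from the mean of all 16 libraries; points are libraries, bars the mean and whiskers the SD (n = 4). WT untrained replicate 2 lies apart for oxidative phosphorylation, at -0.777 against 0.065 to 0.089 in the other WT untrained libraries.

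The difference of training responses was called at 9 genes, 2 higher and 7 lower in Tg relative to WT. At Thap2, Zfc3h1, Gm17167 and Hist1h4m, WT untrained libraries stood apart from all other groups. Thap2 lay between 10.8 and 13.9 CPM in WT untrained and between 5.21 and 7.45 CPM in the other groups. A differing WT untrained group cannot be told apart from a differing training response at these genes. Thap2 (difference of log2FC 1.04, SE 0.151) and Zfc3h1 (0.84, SE 0.135) had positive differences. Apold1 had a difference of -2.38 (SE 0.384, adjusted p = 0.0268). The 5 genes with the smallest p were Gm17167 (-4.71), both gene models named Gm13301 (-6.40 and -4.62), Gm17081 (-5.45) and the histone gene Hist1h4m. Hist1h4m had 0 counts in all 4 WT untrained libraries, so its fitted difference is no measure of size. Nor is that of the Gm13301 model at -6.40: it had 4 counts in WT untrained replicate 4, 0 in the other WT untrained libraries, and a fitted difference of -9.57 without that replicate. Gm17081 (0 to 2 counts) and the other Gm13301 model (0 to 4 counts) were also near the floor in WT untrained libraries. Gm17167 measured 0.264 ± 0.0383 CPM in WT untrained and 5.41 to 6.89 CPM on average in the other groups. The immediate early genes were lower in this contrast (23 of 25 negative, median -1.06, 13 lower adjusted over the list alone; camera adjusted p = 9.07e-23, adjusted p = 0.039 with an estimated correlation). Fos had a difference of -3.69 (SE 0.746, adjusted p = 0.129). Of the 10 called lists it was the only one called with an estimated correlation. Zfc3h1 and Apold1 lost their calls without 7 and 8 of the 16 libraries, each left out singly. Without the 4 libraries high in Myh7, 4 genes were called.

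Training averaged over the genotypes lowered adipocyte markers together with markers of some other non-muscle cells. Of 80 called genes, 34 were higher and 46 lower, and 7 of 15 adipocyte markers were called lower (median -0.74, 11 lower and 2 higher adjusted over the list alone; camera adjusted p = 5.81e-14, adjusted p = 0.0841 with an estimated correlation). Lep fell by 2.87 on the log2 scale (SE 0.46), Cidec by 2.02, Adipoq, the adiponectin gene, by 1.96 and Scd1, a fatty acid desaturase gene, by 1.87. Scd1 measured 93.6 ± 38.6 CPM in WT untrained and 28.0 ± 7.68 in WT trained, and 79.7 ± 49.9 in Tg untrained and 19.98 ± 6.01 in Tg trained libraries. Phgdh, the first enzyme of serine synthesis, fell by 1.03 and Il6st, the shared receptor subunit of the interleukin-6 family, by 0.54. Sbk2, a kinase gene, rose by a log2FC of 0.71 (SE 0.093, adjusted p = 0.00216). The called genes also included Thap2, Zfc3h1, Tmem19 and Entpd4, at which WT untrained libraries stood apart from all other groups. Thap2 lay between 5.21 and 6.68 CPM in Tg untrained and between 6.22 and 7.45 CPM in Tg trained libraries. Calls in this contrast are therefore not all a training response shared by the genotypes. Tendon and cartilage markers (median -0.995, 10 of 11 negative, 9 lower adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), fibroblast markers (median -0.38, 13 of 14 negative, 11 lower adjusted over the list alone; adjusted p = 0.182 with an estimated correlation), macrophage markers (median -0.33, 14 of 18 negative, 1 lower adjusted over the list alone; adjusted p = 0.604 with an estimated correlation) and collagens (median -0.32, 27 of 29 negative, 8 lower adjusted over the list alone; adjusted p = 0.364 with an estimated correlation) fell too. So did the immediate early genes (median -0.50, 25 of 25 negative, 11 lower adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). Endothelial markers rose (median 0.07, 17 of 18 positive, 0 adjusted over the list alone; adjusted p = 0.632 with an estimated correlation), but were not called without WT untrained replicate 2 (median 0.03) or Tg untrained replicate 3 (0.05). Their median was 0.115 without WT untrained replicate 3 and 0.131 without Tg untrained replicate 4. Exercise-responsive regulators rose as a group (median 0.08, 19 of 28 positive, 1 higher adjusted over the list alone; adjusted p = 0.425 with an estimated correlation), with Rcan1 at log2FC 0.28 (adjusted p = 0.103) and Ppargc1a, the PGC-1 alpha gene, at 0.46 (adjusted p = 0.15). The regulators lost their call without Tg untrained replicate 3 (median 0.059, adjusted p = 0.05 as rounded). No list of the 16 called was called with an estimated correlation. Lep and Sbk2 kept their calls without each library left out singly, Scd1 lost its call without Tg trained replicate 4 (adjusted p = 0.0509), and Cidec, Adipoq, Phgdh and Il6st lost theirs without 7, 11, 11 and 12 of the 16. The count moved by over 1.5 times without each of the 16 libraries: 21, 218, 38 and 34 without WT untrained replicates 1 to 4, 34, 16, 30 and 389 without WT trained replicates, 24, 15, 28 and 123 without Tg untrained replicates and 26, 23, 41 and 16 without Tg trained replicates, in order of number. Without the 3 libraries with Alb above 10 CPM it was 584.

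For Tg averaged over training, 196 genes were called, 108 higher and 88 lower. The WT untrained libraries, which stood apart at genes such as Thap2, enter this contrast, so such a difference can add to its calls. The log2FC of Tg without and with training had a Pearson r of 0.229 across genes. Of 87 higher and 43 lower genes called without training and 1 and 1 with it, 1 higher and 0 lower were shared. Myh2, the fast oxidative myosin, measured 439 ± 219 and 590 ± 73.0 CPM in WT and 1194 ± 405 and 1492 ± 381 CPM in Tg, without and with training (log2FC 1.39, SE 0.253, adjusted p = 0.0203). Ucp3, a mitochondrial uncoupling protein gene, fell from 94.1 ± 13.0 and 88.6 ± 16.9 CPM to 65.8 ± 10.2 and 54.7 ± 7.13 CPM (log2FC -0.61, SE 0.101, adjusted p = 0.0142), and Pdk4, a kinase gene that restrains pyruvate oxidation, had a log2FC of -0.57. Of 44 interferon-stimulated genes, 3 were called lower (7 adjusted over the list alone): Ifi204 (-0.99), Ifi207 (-0.91) and Oas2 (-0.76); the list median was -0.11 (adjusted p = 0.61 with an estimated correlation). C3, a complement gene, had a log2FC of -0.93 and Fkbp5, a glucocorticoid-responsive gene, of -1.02. Mt2, a metallothionein gene, had a log2FC of -2.37. Cited2 (0.64), Meox2 (0.56) and Notch3 (0.39) rose. Macrophage and monocyte markers were lower (18 of 18 negative, median -0.70, 0 called, 15 lower adjusted over the list alone; adjusted p = 0.61 with an estimated correlation). Fibroblast markers were lower (median -0.15; adjusted p = 0.786 with an estimated correlation) and tendon and cartilage (median 0.42; adjusted p = 0.711 with an estimated correlation) and Schwann and nerve markers (median 0.43; adjusted p = 0.739 with an estimated correlation) higher, with 3 fibroblast markers lower and 1 higher, 0 tendon and 0 Schwann markers adjusted over the list alone. Endothelial (median 0.14), smooth muscle and pericyte (0.16) and erythroid markers (0.17) were also higher, with adjusted p of 0.711, 0.61 and 0.711 with an estimated correlation. The fibroblast and erythroid calls were lost without 9 and 7 of the 16 libraries, the tendon call without WT trained replicate 2 (median 0.272, against 0.775 without WT trained replicate 4) and the Schwann call without Tg untrained replicate 3 (median 0.238, against 0.251 and called without Tg trained replicate 3). The interferon median was -0.067 without WT trained replicate 1. Without WT untrained replicate 2 the medians were 0.079 for endothelial, 0.086 for smooth muscle and 0.109 for erythroid markers. They were 0.087 for endothelial markers without Tg untrained replicate 4, 0.094 for smooth muscle without Tg untrained replicate 3, and 0.112 for erythroid markers without Tg untrained replicate 1. The fibroblast median was -0.096 and -0.086 without WT trained replicates 1 and 4. Ucp3, Ifi204 and Ifi207 kept their calls without each library left out singly. Myh2 (adjusted p = 0.0521) and Cited2 (0.0529) lost theirs without Tg trained replicate 4, Mt2 without Tg trained replicate 2 or 4 (adjusted p of at most 0.0589) and Oas2 without WT trained replicate 3 or Tg trained replicate 4 (at most 0.056), while Meox2, C3, Notch3, Pdk4 and Fkbp5 did without 7, 8, 8, 11 and 11 of the 16. The count was 351 without WT untrained replicate 2, 374, 70 and 120 without WT trained replicates 2, 3 and 4, 110, 96 and 102 without Tg untrained replicates 1, 2 and 4, and 49, 91 and 29 without Tg trained replicates 2, 3 and 4.

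The list of CHCHD4 and innate immune signalling genes, built from the subject of the study and so not independent evidence, held no called member other than Chchd4 in any contrast, and its camera adjusted p was 0.102 or more. NF-kappaB target genes had a camera adjusted p of 0.0519 or more and medians from -0.163 to -0.014. Across all 17490 genes, the log2FC of training in WT and in Tg had a Pearson r of 0.195, where genes are not independent replicates. It was 0.099 without WT untrained replicate 2, 0.11 without WT trained replicate 2 and 0.295 without WT trained replicate 4. The differences in mean log2 CPM of WT trained and Tg untrained from the shared WT untrained libraries had r = 0.539 and a covariance of 0.0539, against r = 0.498 and a covariance of 0.0281 in simulations of unchanged groups. With the WT untrained libraries split between the comparisons, r was 0.139. Both contrasts called 16 genes higher and 5 lower. Independent lists of these lengths would share 0.09 and 0.017, which leaves out the shared controls, and 20 fits of simulated unchanged groups against shared controls gave 0 shared calls in edgeR, which leaves out real effects. With the WT untrained libraries split, the contrasts shared 5 to 10 higher and 2 to 4 lower genes over the 6 splits, out of 13 to 23 called for training in WT and 10 to 405 for Tg.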

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

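All tests of explanations in this part were chosen or run after the patterns were seen, except the counts over other splits of the libraries. The leave-one-out values behind the tests of a single library had been computed before their predictions were written.

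Of the 22 genes called for training in WT with a position, 15 had another called gene within 500 kb, while 1000 random draws of as many tested genes gave at most 4. Training in both genotypes is argued against: signed by the direction in WT, the median log2FC of the genes was 1.76 in WT and 0.045 in Tg. Training in WT only was not excluded by the bound set for it. Tg untrained, measured against WT untrained libraries not used to pick the genes, had a signed median log2FC of 0.819 to 2.35 over 6 divisions. That explanation needs about 0. The lowest had a standard error over genes of 0.731 and was under 1/2 of the training median of 1.66, the bound for an exclusion. From 19 of 23 to 13 of 13 genes went in the direction of training, which argues against that explanation for most of these genes. Genes of a cluster are not independent. Whether reads shared between near-identical copies within a cluster play a part cannot be told apart. Of the 6 clusters, 1 held both directions, but shared reads can also move copies the same way, and copies elsewhere were not searched. Such copies would add to the 15 neighbouring genes, which the random draws leave out. A candidate explanation is a different genetic background of the WT untrained animals, a hypothesis from the same data that the 15 clustered genes fit. Untrained Tg libraries had 5.21 to 6.68 CPM of Thap2 against 10.8 to 13.9 in WT untrained. Of the 25 genes, 21 were called in the same direction between these groups, with WT untrained libraries shared between the contrasts. Other causes of levels that set WT untrained apart were not tested.

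Macrophage and monocyte markers were lower in trained Tg than in trained WT muscle, with a median log2FC of -0.99. A single library is argued against, since the median nearest to 0 with a library left out was -0.669 (WT trained replicate 4). Whether a lower share of all non-muscle tissue alike was the whole cause cannot be told apart. Tendon and cartilage less macrophage markers lay 1.85 (SE 0.364 between libraries) higher in Tg trained than in WT trained libraries. An exact permutation of the 8 libraries over 9 lists gave p = 0.0286, the smallest that 35 divisions can give. That met the prediction against this explanation. But the test was chosen after the values of the libraries were seen, in place of earlier forms. Macrophage markers were also picked for being low, which raises such differences: they were positive for all 9 lists (0.617 to 1.85). The other 8 lists did not pass in that exact permutation (lowest p = 0.0571), nor did tendon markers by themselves (exact permutation p = 0.114; median log2FC 0.666, 0.373 without WT trained replicate 2 and 1.32 without WT trained replicate 4). Adipocyte (median -0.476) and fibroblast markers (-0.188) were lower, as that explanation needs. The other lists had medians above 0, where it needs values below 0. These were neutrophil 0.99, tendon 0.666, erythroid 0.285, keratinocyte 0.153, Schwann 0.133, endothelial 0.115 and smooth muscle and pericyte markers 0.011. Erythroid markers by themselves had the lowest exact permutation p of the 9 lists (0.0286, not adjusted over the lists). A lower share of some or all non-muscle cells stays open. Fewer macrophages or lower expression of these genes in them stay open too and were not separated. The list's call was lost with an estimated correlation.

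Immediate early genes were lower in trained than in untrained Tg muscle, with a median log2FC of -1.05. A single library is argued against: the median nearest to 0 was -0.878, without Tg untrained replicate 3. Handling of the tissue at sampling cannot be told apart from training, because the heat shock list, with a median of -0.027 and a standard error of 0.153, decides nothing about these genes, and no sampling times are given in the sources used here. Training in Tg stays open as a biological explanation, and so do high levels in the untrained Tg group. With single libraries left out, the list was higher in Tg than in WT without training (median log2FC 0.233 to 0.618). With training, the list was lower in Tg (-0.631 to -0.48). Fos lay between 7.72 and 38.95 CPM in Tg untrained and between 2.23 and 4.45 in Tg trained libraries. It lay between 2.13 and 5.53 CPM in WT untrained and between 2.48 and 13.4 in WT trained libraries.

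The difference of training responses was past its threshold for Thap2 (1.04), Zfc3h1 (0.845), Hist1h4m (-9.29, no measure of size with 0 counts in a group), Gm15737 (-2.35), Gm17081 (-5.45), Apold1 (-2.38), Gm17167 (-4.71) and both Gm13301 models (-4.62 and -6.40, the latter -9.57 without WT untrained replicate 4 and no measure of size). At Thap2, Zfc3h1, Hist1h4m and Gm17167 it was the WT untrained libraries that stood apart from all other groups. Gm17081 and both Gm13301 models were also near the floor in WT untrained libraries. Gm17081 and a Gm13301 model lie in a cluster with Gm17167 on chromosome 4, called higher in trained WT muscle. For lists, the median difference was -0.327 for slow-twitch fibre genes, -0.112 for fatty acid uptake and oxidation, -0.146 for interferon-stimulated genes, 0.076 for cardiolipin synthesis, -1.06 for immediate early genes, -0.67 for macrophage, -0.403 for adipocyte, -0.431 for Schwann and nerve, 0.312 for tendon and cartilage and -0.216 for smooth muscle and pericyte markers. With an estimated correlation the immediate early genes were called (adjusted p = 0.039) and the other lists were not (adjusted p = 0.726). Leaving out single libraries ended the call of cardiolipin synthesis without 9 of the 16, of Schwann and nerve without 8, of fatty acid oxidation and smooth muscle without 7 each, of interferon-stimulated genes without 6, of tendon and cartilage without 5, of adipocyte markers without 3 and of slow-twitch genes and macrophage markers without 1 each (WT trained replicate 3 and WT trained replicate 4, macrophage median -0.268). The tendon median was 0.079 without WT trained replicate 2, 0.199 and 0.473 without WT untrained replicates 4 and 3, 0.618 without Tg untrained replicate 3 and 0.953 without WT trained replicate 4. The Schwann median came to -0.197 without Tg untrained replicate 3 and -0.765 without Tg trained replicate 3, and the smooth muscle median to -0.099 without WT untrained replicate 2. The slow-twitch median was -0.62 without WT untrained replicate 4 and -0.207 without Tg untrained replicate 3, and the adipocyte median -0.639, -0.205 and -0.229 without WT trained replicate 1, Tg untrained replicate 1 and Tg trained replicate 2. The interferon median was -0.06 and -0.081 without WT trained replicate 1 and WT untrained replicate 3, and the cardiolipin median 0.032 without Tg untrained replicate 2. The fatty acid median was 0.018, -0.19 and -0.018 without WT untrained replicate 2, Tg untrained replicate 3 and Tg untrained replicate 4.

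Single libraries stood apart from the other 3 of their group in 27 of 260 groups of values. A rate of 5% would give about 13, but only for independent, normally distributed values. Values of the same library are not independent, and some of the genes, such as Nnt, were picked after their values were seen. The 13 is therefore no firm reference. Of the 27, 10 were WT untrained replicate 2. In that library the median deviation in log2 CPM was -0.239 for disulfide relay substrates, -0.777 for oxidative phosphorylation, -0.523 for fatty acid uptake and oxidation, -0.65 for the tricarboxylic acid cycle, -0.691 for glycolysis, 0.62 for muscle atrophy and autophagy and -0.539 for smooth muscle and pericyte markers, and it had 11.9 CPM of Myod1, 11.2 of Myh7 and 14.9 of Alb. Alb also stood apart in WT trained replicate 4 (35.6 CPM) and Tg untrained replicate 2 (14.97 CPM), against at most 0.236 and 0.201 CPM in the rest of those groups. WT trained replicate 3 had 29.7 CPM of Myh7 and 6.73 of Myl2, and WT trained replicate 1 had 2.90 CPM of Fosb and median deviations of 1.05 for neutrophil and -0.928 for adipocyte markers. WT trained replicate 4 had deviations of 0.038 for glycolysis and -0.114 for circadian clock genes. WT untrained replicate 1 had 13.9 CPM of Thap2 and Tg untrained replicate 1 had 9.21 CPM of Lep. Tg trained replicate 1 had 0.601 CPM of Hist1h4m and a deviation of -0.234 for macrophage markers, and Tg trained replicate 2 one of 0.422 for mitochondrially encoded protein genes. Tg trained replicate 3 had 36.9 CPM of Nnt, 4.25 of Egr1 and a deviation of 0.155 for smooth muscle and pericyte markers.

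Chance is argued against for 5 of the 6 counts of genes above 0, each taken singly. No allowance was made for several counts, and 1 of 35 is the smallest share that 35 splits can give. For training in WT 1 of 35 splits gave as many genes (25 against at most 6 in the others), and for Tg in untrained mice 1 of 35 (130 against 0). For the difference of responses it was 2 of 100 (9, with 9 in another split), for training averaged 1 of 100 (80 against 15) and for Tg averaged 2 of 100 (196, with 387 in another split). That other split exchanged WT trained replicate 2 and Tg trained replicate 1, whose Chchd4 levels fit their labels; what sets it apart was not tested. Chance stays open for Tg in trained mice (2 genes, 2 of 35 splits, 4 at most in the others). For training in Tg the real count was 0, which all 35 splits reach by construction (1 gene at most in the others), so the splits say nothing about it.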

How the results depend on the processing

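The alternatives without libraries high in Alb or Myh7, and without mitochondrial rRNA and 7SL RNA, were chosen after seeing the data. RLE factors, limma-voom, robust dispersion and removal of rRNA kept all 7 counts of genes within 1.5 times. DESeq2 gave 68, 132, 442, 55, 37, 366 and 644 genes for training in WT, training in Tg, Tg untrained, Tg trained, the difference, training averaged and Tg averaged; the cause was not tested. Without a filter, the counts were 5 for training in Tg, 1 for Tg trained and 15 for the difference; the stricter filter gave 1 for Tg trained. Only the 8 libraries compared gave 10, 123, 40 and 5 genes for the pairwise contrasts, with fewer samples behind each spread. Without libraries high in Alb the counts were 42 for training in WT, 104 for training in Tg and 584 for training averaged. Without those high in Myh7 they were 9 for training in Tg, 32 for Tg untrained, 4 for the difference and 41 for training averaged. Replicate numbers gave no clear pairing over all groups: same-numbered libraries had a median r of 0.0015 (-0.153 to 0.176), and 7 of 16 correlated best with their own number. Between Tg trained and Tg untrained, same-numbered libraries had r of 0.058 to 0.176, so a pairing there stays open. Between WT trained and WT untrained they had r of -0.072 to 0.102. With the replicate block, 66 genes were called for Tg untrained, 1 for Tg trained and 16 for training averaged, and the other counts stayed within 1.5 times. The block also ended 43 calls of named genes and lists over the 7 contrasts, and 168 such results stayed called or not called as before.

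Leaving out 1 library gave 16 to 30 genes for training in WT, 0 to 93 for training in Tg, 43 to 138 for Tg untrained, 1 to 16 for Tg trained, 6 to 12 for the difference, 15 to 389 for training averaged and 29 to 374 for Tg averaged. The correlation of training responses ranged from 0.099 to 0.295 and was 0.388 over genes with a mean CPM of at least 10; that of training and Tg effects ranged from 0.46 to 0.608 and was 0.139 with split controls.

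List directions that turned for training in WT without WT untrained replicate 2 were fast-twitch (medians -0.014 to 0.185 over the libraries left out), oxidative phosphorylation (-0.039 to 0.193), tricarboxylic acid cycle (-0.047 to 0.185) and atrophy (-0.228 to 0.088). The same library turned fatty acid oxidation in the difference (-0.19 to 0.018) and oxidative phosphorylation in Tg averaged (-0.013 to 0.097). WT trained replicate 4 turned collagens by the set test in Tg averaged (-0.198 to -0.041). Without libraries high in Alb, training in WT gave -0.012 for oxidative phosphorylation, -0.015 for the tricarboxylic acid cycle and 0.041 for atrophy, the difference gave -0.003 for fatty acid oxidation and Tg averaged gave -0.03 for oxidative phosphorylation. Without those high in Myh7, training in WT gave -0.015 for fast-twitch, -0.057 for oxidative phosphorylation, -0.034 for mitochondrially encoded, -0.06 for tricarboxylic acid cycle and 0.033 for atrophy genes. Schwann markers gave 0.158 for training in Tg, -0.01 for Tg untrained and 0.034 for the difference, slow-twitch genes -0.061 for the difference, and training averaged -0.012 for fast-twitch, -0.022 for fatty acid oxidation and -0.016 for endothelial genes. The cause of these turns was not tested. Over the 7 contrasts, 83 calls of lists were lost with an estimated correlation and 3 held; with fry 81 were lost and 5 held.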

Other observations

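Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase (ENSMUSG00000025453.18, on chromosome 13), varied widely between libraries. It lay between 29.3 and 44.4 CPM in the 4 WT untrained libraries, between 8.97 and 26.8 in WT trained, between 8.83 and 25.2 in Tg untrained and between 6.25 and 36.9 in Tg trained libraries. No contrast called it. Tmem267, the called gene at 119488039 to 119611059 on the same chromosome, measured 15.8 ± 0.696 CPM in WT untrained, 11.2 ± 2.35 in WT trained, 6.08 ± 1.32 in Tg untrained and 8.69 ± 1.70 in Tg trained libraries. Nnt was singled out after its values were seen, and no explanation was tested.

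Of the tested lists, besides the CHCHD4 and innate immune list and the NF-kappaB targets, those that no contrast called were circadian clock genes (camera adjusted p from 0.0627 to 0.958), the integrated stress response and mitochondrial chaperones (0.162 to 0.908), neutrophil markers (0.0608 to 0.815) and keratinocyte markers (0.65 to 0.948). The lymphocyte list had 2 tested members and no set test. Erythroid markers were higher in trained Tg than in trained WT muscle (6 of 6 positive, median 0.28, 0 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation).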
